A study of Mus musculus with 17 samples.

How the data were processed

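The samples are pancreatic islets of C57BL/6 mice, the small clusters of endocrine cells that hold the insulin-producing beta cells. Per the labels, 6 batches of islets were isolated, each pooled from 4 mice and split into portions that were harvested at 0, 24 and 48 h of culture in F12K medium with fetal bovine serum. Each portion was measured on 1 single-colour Affymetrix GeneChip whole-genome mouse expression array, after the RNA had been amplified and labelled with biotin. The 17 arrays used here fall into 5 at 0 h, 6 at 24 h and 6 at 48 h; the 0 h array of batch 5 was not analysed here. Groups and batches were taken from the labels and the study's design text.

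The deposited values are on a log2 scale, 1 per probe set and array, and were made by the authors with RMA, per the submitters' processing notes; its version is not given in the sources used here. RMA subtracts background, quantile-normalizes the arrays against each other and summarises the probes of each probe set, so that a change shared by most transcripts is removed and differences of weakly expressed genes are compressed. The base of the logarithm was inferred from the deposited values, which ran from 1.55 to 13.81. No detection call accompanied the values used here, so a level near the table's median of 3.52 was not separated from background. The number of arrays per time limits the precision.

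The table held 45101 probe sets, of which 64 controls were left out and 45037 were tested without a filter on level. The platform's probe annotation paired 34945 of these with 1 gene symbol and 932 with several, and did not list 9160. Of the probe sets with 1 symbol, 34741 had an Entrez ID in the RefSeq gene table, and 0 symbols changed on the update. No gene was named from a probe set with several symbols. A gene with more than 1 probe set, as 9010 of the 18193 genes had, was represented by the one with the highest mean over all 17 arrays. Probe sets of the same gene that passed the test in opposite directions were found for 22 genes at 24 h and 24 genes at 48 h against 0 h, and for 0 genes at 48 h against 24 h.

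The 3 comparisons (24 h against 0 h, 48 h against 0 h, 48 h against 24 h) were tested with limma (version 3.58.1 in R 4.3.3), with 1 mean per time fitted to all 17 arrays by lmFit, moderated by eBayes, and Benjamini-Hochberg adjustment over the 45037 probe sets of each comparison. A probe set passed at an adjusted p under 0.05, and 2-fold counts also required a log2 difference of at least 1. Errors of log2 differences are limma's standard errors (SE). A rule of selection from the study's design text, a mean signal above 4-fold or under 0.25-fold of that at 0 h on the linear scale, was applied as written, with no test. 29 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over 87 tests (29 lists in 3 comparisons). The lists held 546 genes, of which 489 had a probe set with 1 symbol. Calls are also given with the correlation estimated for each list, and with fry. Counts of list members that passed are over all probe sets unless they are said to be adjusted over the list alone. Tests of single values between times were exact permutation tests, two-sided. The test of whether the members of a list moved alike used a one-sided heterogeneity statistic over all 462 permutations of the time labels.

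The groups, tests, gene lists, rule for named genes and most alternatives were set before the data were examined. Named genes are, among genes above the median level that passed with no overlap between the arrays of the 2 times, the 10 largest rises and 10 largest falls against 0 h and the 5 of each between 48 and 24 h, up to 4 passing members of each list, and a fixed set of hormones, beta cell genes and Actb. The alternatives were the batch as a fixed or random block, complete batches, array weights, another variance prior, median centring, quantile normalization again, a filter on level, leaving out probe sets of the _x_at and _s_at kinds, fitting only the arrays compared, other ways to summarise probe sets, and leaving out each array in turn. Leaving out 2 arrays that stood apart and adding the mean of the acinar markers as a covariate were chosen after seeing the data. Setting a floor before taking logarithms was not run, as the deposited values were already on a log2 scale.

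The pairing of arrays by batch comes from the study's design text. Over the 16 pairs of arrays of the same batch, the correlation of their deviations from the means of their times had a median of 0.00545 (range -0.159 to 0.274) and was above 0.1 in 4 pairs. For the 80 pairs of different batches the median was -0.00978 and the highest value 0.366, and 3 of 17 arrays correlated best with an array of their own batch. limma's consensus correlation within a batch was 0.0183. The fit with the batch as a block called 3640, 3572 and 224 probe sets in the 3 comparisons, and its value is printed beside a result where it changed the call.

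The tests were tested on simulated data in which 200 of 45037 probe sets were changed. The changed ones were drawn from probe sets above the median level, and the noise was independent between probe sets. Recovery among dimmer probe sets and false calls under correlated noise were therefore not tested. For 24 h against 0 h, 42% of changes of 0.5 on the log2 scale, 92% of those of 1 and 100% of those of 2 were recovered, and 92% of those of -1, with 9 false calls. For 48 h against 24 h the shares were 54%, 98% and 100%, and 88% of changes of -1, with 8 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.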

Results

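Expression was measured over 45037 probe sets in mouse islets at 0 h (n = 5 batches), 24 h (n = 6) and 48 h (n = 6) after isolation, each batch being a separate pool of islets from 4 mice. The arrays had median levels between 3.47 and 3.57 on the log2 scale, and every pair of arrays correlated at 0.976 to 0.995 across probe sets. The gap between the 3' and 5' probe sets of actin, a measure of RNA degradation, was 2.14 ± 0.11 (SD, n = 5) at 0 h, 2.10 ± 0.15 (SD, n = 6) at 24 h and 2.02 ± 0.13 (SD, n = 6) at 48 h. The lowest of the 3 exact permutation p between times was 0.126 (0.463 adjusted over 6 tests). The signal for 18S ribosomal RNA was 11.95 at 0 h, 11.90 at 24 h and 11.78 at 48 h, with a lowest exact p of 0.203. Replicate 3 at 0 h and replicate 5 at 24 h had the lowest median correlation with the other arrays of their own time, 0.987 and 0.988. The first principal component held 26.3% of the variance and separated the 0 h arrays from the others, and the second held 10.8%.

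**Figure D1:**
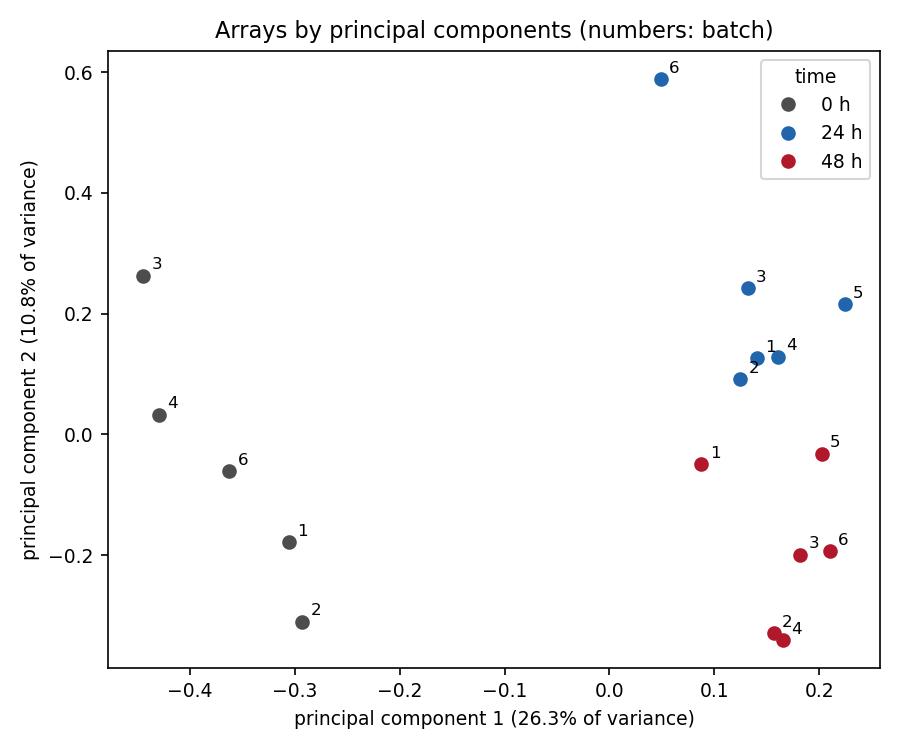
Each point is 1 array, placed by its first principal component (26.3% of the variance) and second (10.8%), coloured by time and numbered by batch. The 5 arrays at 0 h lie at negative values of the first component and the 12 cultured arrays at positive values, where 24 h replicate 6 has the highest second component (0.589).

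The first comparison asked how islet transcripts differed after 24 h of culture from those of freshly isolated islets. Gsdma, a member of the gasdermin family, showed the largest measured rise, from 3.94 ± 0.80 (SD, n = 5) to 8.51 ± 0.35 (SD, n = 6), which was at least 23.7-fold (log2 difference 4.57 ± 0.28, adjusted p = 5.17e-09). Lcn2, which encodes the iron-siderophore-binding lipocalin 2, was at least 16.4-fold higher (4.03 ± 0.68, adjusted p = 0.000629), although 24 h replicate 5 stood at 3.66 against 6.55 to 7.75 on the other arrays of that time, and without it the difference was 4.64. Trib3, a pseudokinase induced by stress signalling, was 11.8-fold higher (3.56 ± 0.21, adjusted p = 3.36e-09). Among genes that met the rule for named genes, the largest measured fall was in Cavin2, which encodes a component of caveolae. It fell from 6.64 ± 0.39 (SD, n = 5) to 2.72 ± 0.22 (SD, n = 6), at least 15.2-fold (-3.92 ± 0.15, adjusted p = 1.29e-11). Lcn2 and Tfpi2 at 0 h and Cavin2 at 24 h lay under the table's median of 3.52, where signal was not separated from background, so that their folds are lower bounds and their ranks those of the measured values. Gsdma at 0 h was under that median on replicates 3 and 4 (3.09 on each), so its fold is a lower bound too.

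The other large rises at 24 h were in Tfpi2 (log2 difference 3.49), Crybb3 (3.32), Rgs4 (2.99), Gbp6 (2.78), Igfbp5 (2.52), Hmox1 (2.42) and Ier3 (2.37). The other large falls were in Btnl9 (-3.68), Rgs5 (-3.07), Rgcc (-3.04), Timp3 (-3.02), Rgs2 (-2.89), Cav1 (-2.75), Pbk (-2.45), Ptprb (-2.34) and Epas1 (-2.30). Rgcc at 24 h was under the table's median on replicates 3 and 5 (3.48 and 2.43), so its fall is a lower bound. Rgs5 is a marker of pericytes, the contractile cells that surround capillaries, and Ptprb and Epas1 are strongly expressed in endothelium. Probe sets of the same gene differed in size for several of these: those of Rgs4 ranged from 0.51 to 3.30, of Igfbp5 from 0.19 to 2.52, of Cavin2 from -3.92 to 0.14, of Ptprb from -2.34 to 0.10 and of Epas1 from -2.30 to 0.01.

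**Figure D2:**
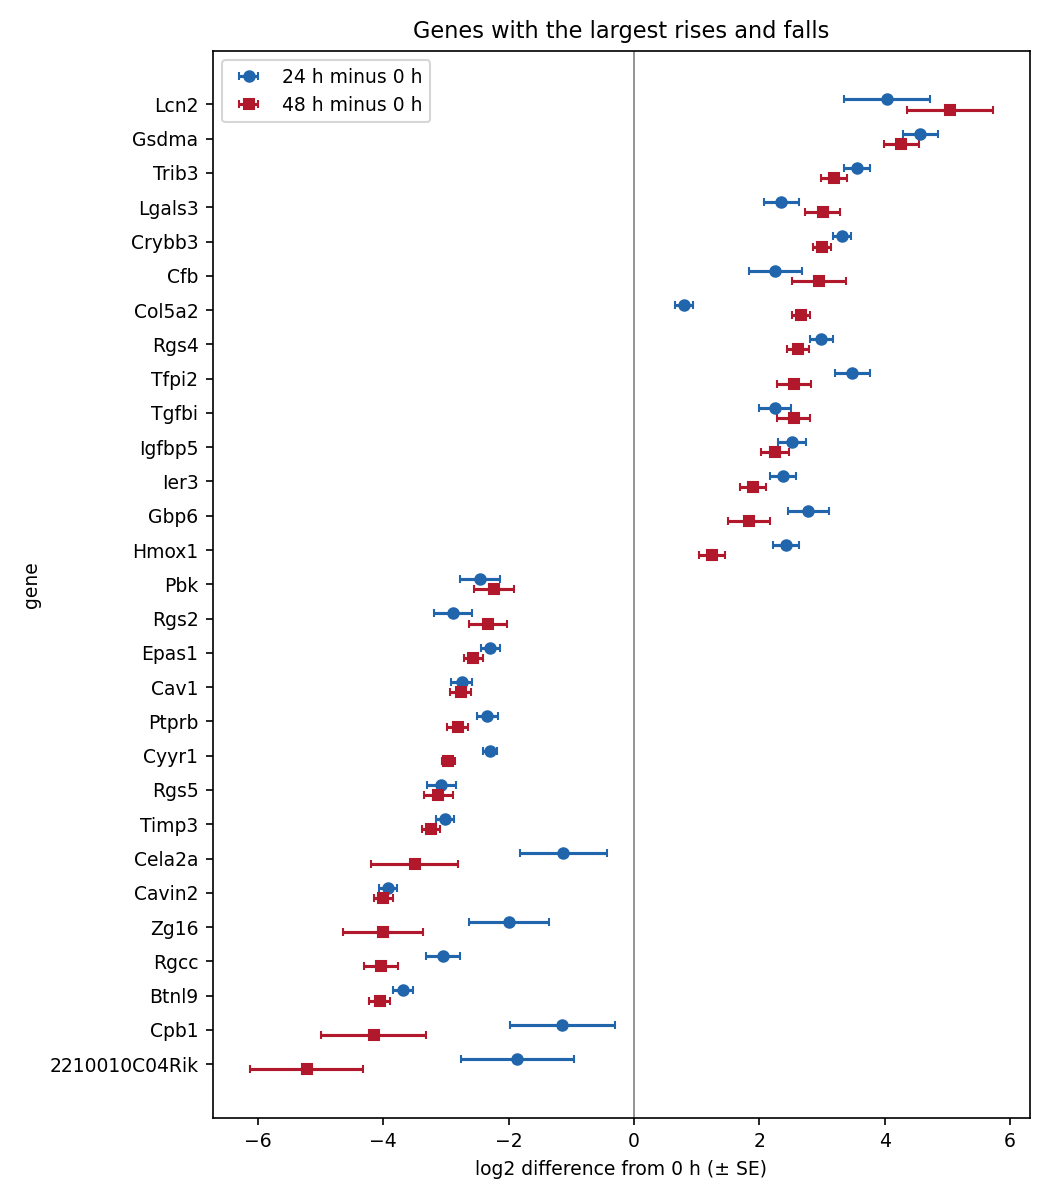
Log2 differences from 0 h (horizontal axis, points with SE bars) of the genes named as the largest rises and falls, at 24 h (circles) and 48 h (squares). Lcn2 reaches 5.04 and Gsdma 4.27 at 48 h, while 2210010C04Rik stands at -5.23 and Cpb1 at -4.16 at 48 h with wider bars than Cavin2 (-4.00).

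Genes of the beta cell fell in part at 24 h. Of 21 measured members of the list for beta cell identity and function, 0 rose, 11 fell and 10 did not pass, and 12 fell when adjusted over the list alone (median log2 difference -0.31, camera adjusted p = 1.24e-06, adjusted p = 0.0327 with an estimated correlation). Slc2a2, the glucose transporter of rodent beta cells, fell from 12.24 ± 0.07 (SD, n = 5) to 11.49 ± 0.14 (SD, n = 6), a log2 difference of -0.75 ± 0.08 (adjusted p = 2.88e-06). The ion channel gene Trpm5 fell by 1.48, the peptide hormone gene Ucn3 by 0.80 and the transcription factor gene Nkx6-1 by 0.75. Pdx1, a transcription factor of beta cells, differed by -0.38 ± 0.11 (adjusted p = 0.0440), a call lost in 12 of the 17 fits that left out 1 array (highest adjusted p = 0.122, without 0 h replicate 1). The transcripts for insulin, amylin and glucagon did not pass: Ins2 stood at 13.76 at 0 h and 13.73 at 24 h, Iapp at 13.02 and 13.10, and Gcg at 12.81 and 12.77, all near the top of the scale, where a change could be compressed.

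Of 9 measured genes of other endocrine cells, 0 rose and 5 fell at 24 h, against 1 and 5 adjusted over the list alone (median -0.44, camera adjusted p = 0.0123, adjusted p = 0.338 with an estimated correlation). Ppy, the hormone of gamma cells, fell from 11.43 ± 0.34 (SD, n = 5) to 9.96 ± 0.56 (SD, n = 6), a log2 difference of -1.47 ± 0.35 (adjusted p = 0.0116). Sst, the hormone of delta cells, fell by 1.27 on the log2 scale (SE 0.25, adjusted p = 0.00272). Pyy (-0.78) and Hhex (-0.72) passed with adjusted p = 0.0472 and 0.0282, calls lost in 11 and 5 of the 17 fits that left out 1 array, with the highest p without 0 h replicate 1 (0.109 and 0.0780). Actb, a common reference gene, differed by -0.29 ± 0.12 (adjusted p = 0.180).

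Genes of the antioxidant and metal response rose at 24 h. Of 19 measured members of the oxidative stress list, 13 rose and 0 fell, and 15 rose when adjusted over the list alone (median 0.64, camera adjusted p = 2.13e-15, adjusted p = 0.000583 with an estimated correlation). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 5.37-fold (2.42 ± 0.21, adjusted p = 4.47e-07), and the metallothionein gene Mt2 rose 4.35-fold (2.12 ± 0.21). Gstm1 rose by 1.69 ± 0.09 and Gclm, which encodes a subunit of the enzyme that starts glutathione synthesis, by 1.41 ± 0.17. The list mean was higher at 24 h in 5 of 5 batches with both times, by 0.664 to 0.968.

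Interferon-stimulated genes were also higher at 24 h. Of 18 measured, 11 rose and 0 fell, and 13 rose when adjusted over the list alone (median 0.88, camera adjusted p = 8.03e-12). That call was lost with an adjusted p = 0.110 with an estimated correlation. Ifit3 rose 3.17-fold (1.67 ± 0.26, adjusted p = 0.000292), Gbp3 and the regulator Irf7 rose by 1.57 ± 0.26 and 1.57 ± 0.28, and Gbp2, under the table's median at 0 h, by at least 1.64 ± 0.36. The list mean was higher in 5 of 5 batches (0.469 to 1.49), but 24 h replicate 5, from the batch whose 0 h array was not analysed here, stood at 5.45 against 5.14 to 5.51 on the 0 h arrays. Markers of lymphocytes did not pass (0 of 11) and those of macrophages were lower at this time.

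Chemokine and cytokine genes moved in the same direction, with 5 of 29 measured members higher and 1 lower (7 and 1 adjusted over the list alone, median 0.10, camera adjusted p = 0.00686, adjusted p = 0.0424 with an estimated correlation). Only 13 of the 29 were above the median level. Ccl5 rose by 1.97 ± 0.17 (adjusted p = 4.38e-07), Cxcl10 by 1.46 ± 0.36 (adjusted p = 0.0147) and Cxcl16 by 0.82 ± 0.13. Cxcl10 stood at 7.46 on 24 h replicate 4, against 4.15 to 5.58 on the other arrays of that time. Of 21 NF-kappaB target genes, 6 rose and 0 fell (6 and 1 adjusted over the list alone, median 0.22, camera adjusted p = 0.00239, adjusted p = 0.172 with an estimated correlation). Among them Bcl3 rose by 1.49 ± 0.23, the adhesion molecule gene Icam1, under the table's median at 0 h, by at least 1.38 ± 0.31 and Sod2, the mitochondrial superoxide dismutase, by 0.66 ± 0.08. Probe sets of Sod2 ranged from -0.32 to 0.66. Without 0 h replicate 3 the median of the NF-kappaB list was 0.12.

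Several further stress groups held risen members at 24 h. Of 20 genes of the unfolded protein response, 7 rose and 3 fell (9 and 6 adjusted over the list alone), and the list as a whole did not pass (median 0.14, camera adjusted p = 0.0714). The members that rose included Chac1 (2.03 ± 0.19), Sesn2 (1.21 ± 0.26) and Ddit3 (1.13 ± 0.17), which are induced through ATF4, whereas the chaperone gene Calr was lower (-0.85). Of 12 p53 target genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.00142, adjusted p = 0.110 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a (1.76 ± 0.14, adjusted p = 2.31e-07) and the nuclease gene Aen (0.95 ± 0.14). Of 16 pro-apoptotic and death receptor genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.0280, adjusted p = 0.110 with an estimated correlation). These were Tnfrsf12a (0.92 ± 0.18), Tnfrsf1a (0.84 ± 0.10) and Pmaip1, whose level lay under the table's median on every array and was not separated from background. The pro-apoptotic call was lost without 0 h replicate 6 (adjusted p = 0.0558), and its median was 0.09 without 24 h replicate 6.

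Glycolytic genes were higher at 24 h, with 4 of 14 past the test and 0 lower (9 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 6.84e-05, adjusted p = 0.261 with an estimated correlation). Aldoa rose by 0.94 ± 0.11 (adjusted p = 1.24e-05), Pfkp by 0.95 ± 0.21 and Pgk1 by 0.77 ± 0.19. Among the 24 h arrays all 3 were highest on replicate 1, whose glycolysis list mean was 8.10 against 6.92 to 7.53 on the others, and without that array they stood at 0.85, 0.73 and 0.62 and the list's median at 0.53. Genes of the cell cycle and DNA replication fell in 11 of 23 cases and rose in 0 (15 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 1.34e-07, adjusted p = 0.110 with an estimated correlation). The proliferation marker Mki67 fell from 6.79 ± 0.50 (SD, n = 5) to 4.70 ± 0.43 (SD, n = 6), Top2a fell by 1.84 on the log2 scale and Rrm2, under the table's median at 24 h, by at least 2.05.

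Markers of other cell types in the islet preparation moved as well. Of 22 macrophage and dendritic cell markers, 10 fell and 1 rose at 24 h (14 and 1 adjusted over the list alone, median -0.54, camera adjusted p = 9.31e-08, adjusted p = 0.110 with an estimated correlation). The class II antigen genes H2-Aa (-1.69 ± 0.19) and H2-Eb1 (-1.62 ± 0.13) and the growth factor receptor gene Csf1r (-1.58 ± 0.14) fell, whereas Cd68, which encodes a lysosomal protein, rose from 3.79 ± 0.17 (SD, n = 5) to 5.63 ± 0.35 (SD, n = 6). Of 17 endothelial markers, 6 fell and 2 rose (6 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.0280, adjusted p = 0.342 with an estimated correlation), with Ptprb at -2.34 ± 0.17, Plvap at -1.94 ± 0.17 and the receptor gene Flt1 at -1.44 ± 0.15. Of 17 fibroblast and stellate cell markers, 5 fell and 1 rose (6 and 1 adjusted over the list alone, median -0.16, camera adjusted p = 0.0229, adjusted p = 0.245 with an estimated correlation), including the smooth muscle actin gene Acta2 (-1.66 ± 0.17) and Col3a1 (-1.10 ± 0.21). Probe sets of Flt1 ranged from -1.44 to 0.19 and those of Acta2 from -1.66 to -0.06. Without 0 h replicate 3 the medians of the endothelial and fibroblast lists were -0.10 and -0.08.

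Of 22 acinar markers, which stand for the digestive-enzyme cells of the exocrine pancreas, 2 fell and 0 rose at 24 h (4 and 0 adjusted over the list alone, median -0.50, camera adjusted p = 0.0318, adjusted p = 0.604 with an estimated correlation). The acinar list mean varied widely within a time, from 4.95 to 7.25 at 0 h and from 4.04 to 6.14 at 24 h. Without 0 h replicate 4, the highest of the 0 h arrays, the list's median was -1.19e-05 and the call was lost (adjusted p = 0.325). The acinar mean was lower at 24 h in 2 of 5 batches and higher in 3. The pair of members that fell were Bhlha15 (-0.82 ± 0.13, adjusted p = 0.000461) and Clps (-1.07 ± 0.32, adjusted p = 0.0405, or 0.0543 with the batch as a block). Bhlha15, also expressed outside acinar cells, stood at 9.26 to 9.72 on the 0 h arrays, a much narrower spread than that of the acinar list mean. Both were lowest on 0 h replicate 1 and highest on 0 h replicate 4. Clps at 24 h lay close to the table's median, with some arrays under it, so its fall is a lower bound. Without 0 h replicate 4 Clps stood at -0.63. The other probe set of Clps fell by 2.25 (adjusted p = 0.00213).

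At 24 h against 0 h, 3862 of 45037 probe sets passed, of which 1737 rose and 2125 fell; 497 of them changed at least 2-fold (263 up, 234 down). Of 18193 genes, 2201 passed by the probe set that represents them. Of 11931 genes above the median level, 1452 had no overlap between the arrays of both times, a share that chance would set at 0.433%, and 1318 of these passed. The median log2 difference over all probe sets was -0.00644. Camera called 14 of 29 lists, of which 3 held with an estimated correlation (beta cell, chemokine and oxidative stress lists), and fry called 19 but not the acinar list (adjusted p = 0.222).

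The second comparison set 48 h of culture against 0 h. Lcn2 showed the largest measured rise, from 2.65 ± 0.26 (SD, n = 5) to 7.69 ± 1.49 (SD, n = 6), which was at least 32.9-fold (5.04 ± 0.68, adjusted p = 9.01e-05). Gsdma was at least 19.3-fold higher (4.27 ± 0.28, adjusted p = 1.10e-08), as it lay under the table's median on 0 h replicates 3 and 4. Lgals3, which encodes the lectin galectin 3, was 8.05-fold higher (3.01 ± 0.28, adjusted p = 1.18e-06). Col5a2, a fibrillar collagen gene, rose from 3.99 ± 0.06 (SD, n = 5) to 6.65 ± 0.32 (SD, n = 6). The largest measured falls included pancreatic enzyme genes. The trypsinogen-family gene 2210010C04Rik fell at least 37.4-fold (-5.23 ± 0.90, adjusted p = 0.000868), the carboxypeptidase gene Cpb1 at least 17.8-fold (-4.16 ± 0.84, adjusted p = 0.00349), and Btnl9 at least 16.6-fold (-4.06 ± 0.16, adjusted p = 1.68e-11). Lcn2 and Tfpi2 at 0 h and 2210010C04Rik, Cpb1, Rgcc and Cavin2 at 48 h lay under the table's median, so that their folds are lower bounds and their ranks those of the measured values. At 48 h Btnl9, Zg16 and Cela2a lay close to that median, with some arrays under it, and their falls are lower bounds too. The log2 differences of 2210010C04Rik, Cpb1 and Cela2a were -4.59, -3.44 and -2.82 without 0 h replicate 4.

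The other large rises at 48 h were in Trib3 (3.19), Crybb3 (3.00), Cfb (2.95), Rgs4 (2.62), Tfpi2 (2.55) and Tgfbi (2.55), and the other large falls in Rgcc (-4.04), Zg16 (-4.01), Cavin2 (-4.00), Cela2a (-3.50), Timp3 (-3.23), Rgs5 (-3.12) and Cyyr1 (-2.96). Probe sets of Col5a2 ranged from 0.62 to 2.67, of Zg16 from -4.01 to -0.67, of Cavin2 from -4.00 to -0.09 and of 2210010C04Rik from -5.23 to -0.32. Within 48 h, replicate 5 stood apart for the enzyme genes, with Cpb1 at 5.45 against 2.45 to 2.79 on the other arrays and 2210010C04Rik at 5.14 against 2.04 to 3.03.

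Of 22 acinar markers, 8 fell and 0 rose at 48 h against 0 h, and 15 fell when adjusted over the list alone (median -1.55, camera adjusted p = 6.82e-09, adjusted p = 0.237 with an estimated correlation). Zg16 fell by at least 4.01, Cela2a by at least 3.50 and Cela3b by 2.80 on the log2 scale. Cela3b had an adjusted p = 0.0254, or 0.0708 with the batch as a block and 0.0835 without 0 h replicate 4. The acinar list mean was 5.67 ± 0.93 (SD, n = 5) at 0 h and 4.05 ± 0.44 (SD, n = 6) at 48 h and was lower in 5 of 5 batches, by between -3.34 and -1.01. Without 0 h replicate 4 the list's median was -0.96.

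Endothelial markers were lower at 48 h, with 10 of 17 past the test and 0 higher (11 and 1 adjusted over the list alone, median -0.40, camera adjusted p = 5.40e-09, adjusted p = 0.0327 with an estimated correlation). Ptprb (-2.82 ± 0.17), Plvap (-2.63 ± 0.17), Flt1 (-1.90 ± 0.15) and Kdr, a receptor for vascular endothelial growth factor (-1.87 ± 0.18), fell most, whereas Cdh5 and Pecam1, under the table's median at all 3 times, did not pass (-0.21 and -0.18). Probe sets of Ptprb ranged from -2.82 to 0.16. The list mean was lower in 5 of 5 batches, by between -1.15 and -0.614. Of 22 macrophage and dendritic cell markers, 6 fell and 2 rose (7 and 3 adjusted over the list alone, median -0.12, camera adjusted p = 0.0314, adjusted p = 0.434 with an estimated correlation), a call lost without 0 h replicate 3 or 48 h replicate 6 (highest adjusted p = 0.0883). The median of this list was -0.06 without 48 h replicate 2. H2-Aa, H2-Eb1 and H2-Ab1 fell by 2.58, 2.43 and 2.23 on the log2 scale and Cd68 rose by 2.16 ± 0.15.

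**Figure D3:**
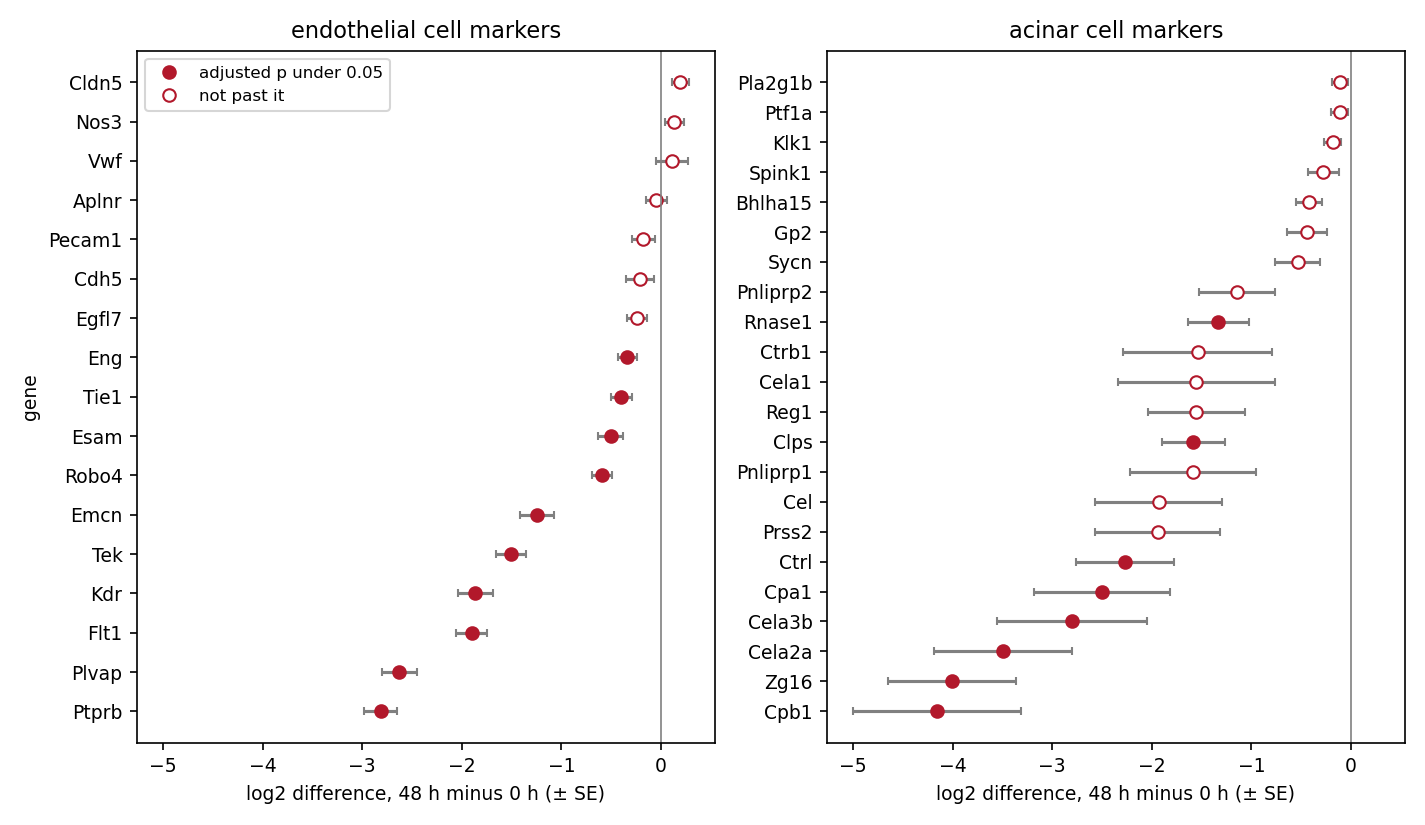
Log2 differences between 48 h and 0 h (horizontal axis, points with SE bars) of each measured endothelial marker (left) and acinar marker (right), filled where the adjusted p was under 0.05. Ptprb (-2.82) and Plvap (-2.63) lie far below Cdh5 (-0.21) and Pecam1 (-0.18), both under the table's median level at 0 h, and Cpb1 (-4.16) far below Bhlha15 (-0.42).

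Fibroblast and stellate cell markers went both ways at 48 h, with 5 of 17 higher and 2 lower (5 and 3 adjusted over the list alone, median 0.02, camera adjusted p = 0.188). The intermediate filament gene Vim rose by 1.85 ± 0.16, Col3a1 by 1.71 ± 0.21 and Col1a2 by 0.99 ± 0.15, whereas Tagln fell by 0.79 on the log2 scale. Probe sets of Col1a2 ranged from -0.06 to 0.99.

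The oxidative stress list was higher at 48 h, with 11 of 19 members up and 0 down (14 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 5.40e-09, adjusted p = 0.00593 with an estimated correlation). Mt2 rose by 1.77 ± 0.21, Gstm1 by 1.29 ± 0.09 and Hmox1 by 1.25 ± 0.21. Of 20 genes of the unfolded protein response, 8 rose and 2 fell (10 and 4 adjusted over the list alone, median 0.10, camera adjusted p = 0.00686, adjusted p = 0.310 with an estimated correlation), led by Trib3, Chac1 (2.00 ± 0.19) and Ddit3 (0.94 ± 0.17). The median of this list was 0.15 without 0 h replicate 3. Glycolytic genes rose in 6 of 14 cases and fell in 0 (10 and 1 adjusted over the list alone, median 0.74, camera adjusted p = 4.50e-05, adjusted p = 0.254 with an estimated correlation), among them Pfkp by 1.01 and Hk2 by at least 1.01. Hk2 at 0 h lay close to the table's median, with replicates 1 and 2 under it. Of 12 p53 target genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.07, camera adjusted p = 0.0352, adjusted p = 0.254 with an estimated correlation), with Cdkn1a at 1.30 ± 0.14. The p53 call was lost without 48 h replicate 1 or 2 (highest adjusted p = 0.0669), and its median was 0.04 without replicate 2.

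Inflammatory groups did not pass as lists at 48 h. Of 18 interferon-stimulated genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 0.0724, or 0.00612 with the batch as a block), and these were the immunoproteasome genes Psmb8 (1.01 ± 0.08) and Psmb9 (0.69 ± 0.08) and B2m (0.69 ± 0.21). The call of B2m was lost in 12 of the 17 fits that left out 1 array, with the highest p without 0 h replicate 2 (0.104). Of 29 chemokines and cytokines, 2 rose and 0 fell (2 and 0 adjusted over the list alone, median 0.06, camera adjusted p = 0.125), Ccl5 by 1.00 ± 0.17 and Cxcl16 by 0.88 ± 0.13. Of 21 NF-kappaB target genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.0968, or 0.0268 with the batch as a block), with Bcl3 at 1.10 ± 0.23. Of 16 pro-apoptotic genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.05, camera adjusted p = 0.125), namely Tnfrsf1a (0.49 ± 0.10).

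Cell cycle genes stayed below their 0 h level, with 10 of 23 lower and 0 higher (12 and 0 adjusted over the list alone, median -0.36, camera adjusted p = 9.53e-08, adjusted p = 0.110 with an estimated correlation). Cdc20 fell by 2.27 on the log2 scale, Mki67 by 2.13 and Cdk1, under the table's median at 48 h, by at least 1.61. Of 21 beta cell genes, 7 fell and 2 rose (9 and 2 adjusted over the list alone, median -0.16, camera adjusted p = 0.00327, adjusted p = 0.141 with an estimated correlation). Trpm5 stood at -1.20 ± 0.15, Slc30a8, the zinc transporter of insulin granules, at -0.46 ± 0.10 and Slc2a2 at -0.45 ± 0.08, while the transcription factor gene Mnx1 stood at 0.51 ± 0.13 (adjusted p = 0.0142, or 0.0514 with the batch as a block). Pdx1 did not pass (-0.14, adjusted p = 0.543), nor did Ins2 (-0.07), Iapp (-0.02), Gcg (-0.16) or Actb (-0.17).

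Of 9 other endocrine genes, 2 fell and 0 rose at 48 h (3 and 0 adjusted over the list alone, median -0.31, camera adjusted p = 0.0118, adjusted p = 0.338 with an estimated correlation). Sst fell by 1.31 on the log2 scale (SE 0.25, adjusted p = 0.00249) and Ttr by 0.36 (SE 0.07). Ppy stood at -1.14 ± 0.35 (adjusted p = 0.0552, or 0.00944 with the batch as a block). Without 0 h replicate 1 the median of this list was -0.18.

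At 48 h against 0 h, 3815 probe sets passed, of which 2102 rose and 1713 fell, and 419 changed at least 2-fold (209 up, 210 down). By the probe set that represents them, 2133 genes passed. No overlap between the arrays of both times was seen for 1510 of 11931 genes above the median level (0.433% by chance), and 1308 of these passed. Adding the acinar list mean of each array as a covariate, a choice made after seeing the data, lowered the count of 3815 to 1100. In that fit 365 probe sets passed at 2-fold (against 419) and 10 lists were called (against 12). The acinar mean ran from 4.95 to 7.25 at 0 h and from 3.74 to 4.93 at 48 h, without overlap. The covariate thus takes up part of the difference between these times, and the lower count cannot tell acinar content from time. Camera called 12 of 29 lists, of which the endothelial and oxidative stress lists held with an estimated correlation, and fry called 16.

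The third comparison set 48 h against 24 h of culture. Col3a1 showed the largest rise, from 5.03 ± 0.25 (SD, n = 6) to 7.85 ± 0.41 (SD, n = 6), 7.04-fold (2.82 ± 0.20, adjusted p = 7.32e-07), and Col5a2 rose 3.64-fold (1.86 ± 0.13, adjusted p = 7.32e-07). Clec7a, which encodes the beta-glucan receptor dectin-1 of myeloid cells, rose 3.36-fold (1.75 ± 0.16, adjusted p = 3.05e-05), and the lysozyme genes Lyz1 and Lyz2 rose by 1.70 ± 0.31 (adjusted p = 0.0162) and 1.54 ± 0.18 (adjusted p = 0.000727). The largest falls were in Ifit3 (-1.57 ± 0.25, adjusted p = 0.00695), the matrix protein gene Thbs1 (-1.33 ± 0.21, adjusted p = 0.00790), Hmox1 (-1.18 ± 0.20, adjusted p = 0.0107), Nrip2 (-1.13 ± 0.18) and Cyb5r1 (-1.11 ± 0.22). Probe sets of Col3a1 ranged from 0.48 to 2.82 and those of Lyz1 from 0.21 to 1.70. The call of Cyb5r1 was lost in 7 of the 17 fits that left out 1 array (highest adjusted p = 0.0724, without 24 h replicate 1) and that of Lyz1 without 48 h replicate 2 (0.0511).

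Fibroblast and stellate cell markers rose as a list between 24 and 48 h, with 5 of 17 higher and 0 lower (8 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 6.99e-08, adjusted p = 0.0182 with an estimated correlation). Besides Col3a1, Col1a2 rose by 1.48 ± 0.14, Acta2 by 1.13 ± 0.16 and Vim by 0.88 ± 0.15. The list mean was higher in 6 of 6 batches, by 0.194 to 0.664, and the median was 0.10 without 24 h replicate 1. Endothelial markers were lower again, with 3 of 17 past the test and 0 higher (12 and 0 adjusted over the list alone, median -0.38, camera adjusted p = 6.11e-13, adjusted p = 0.0123 with an estimated correlation), and the list mean was lower in 6 of 6 batches. The members were Kdr (-0.83 ± 0.17), Robo4 (-0.48 ± 0.09) and Egfl7 (-0.47 ± 0.10), the last with an adjusted p = 0.0383, or 0.0959 with the batch as a block and 0.0827 without 24 h replicate 1. The calls of Kdr and Robo4 were each lost in 5 of the 17 fits that left out 1 array, with the highest p without 48 h replicate 2 (0.0778 and 0.0741).

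**Figure D4:**
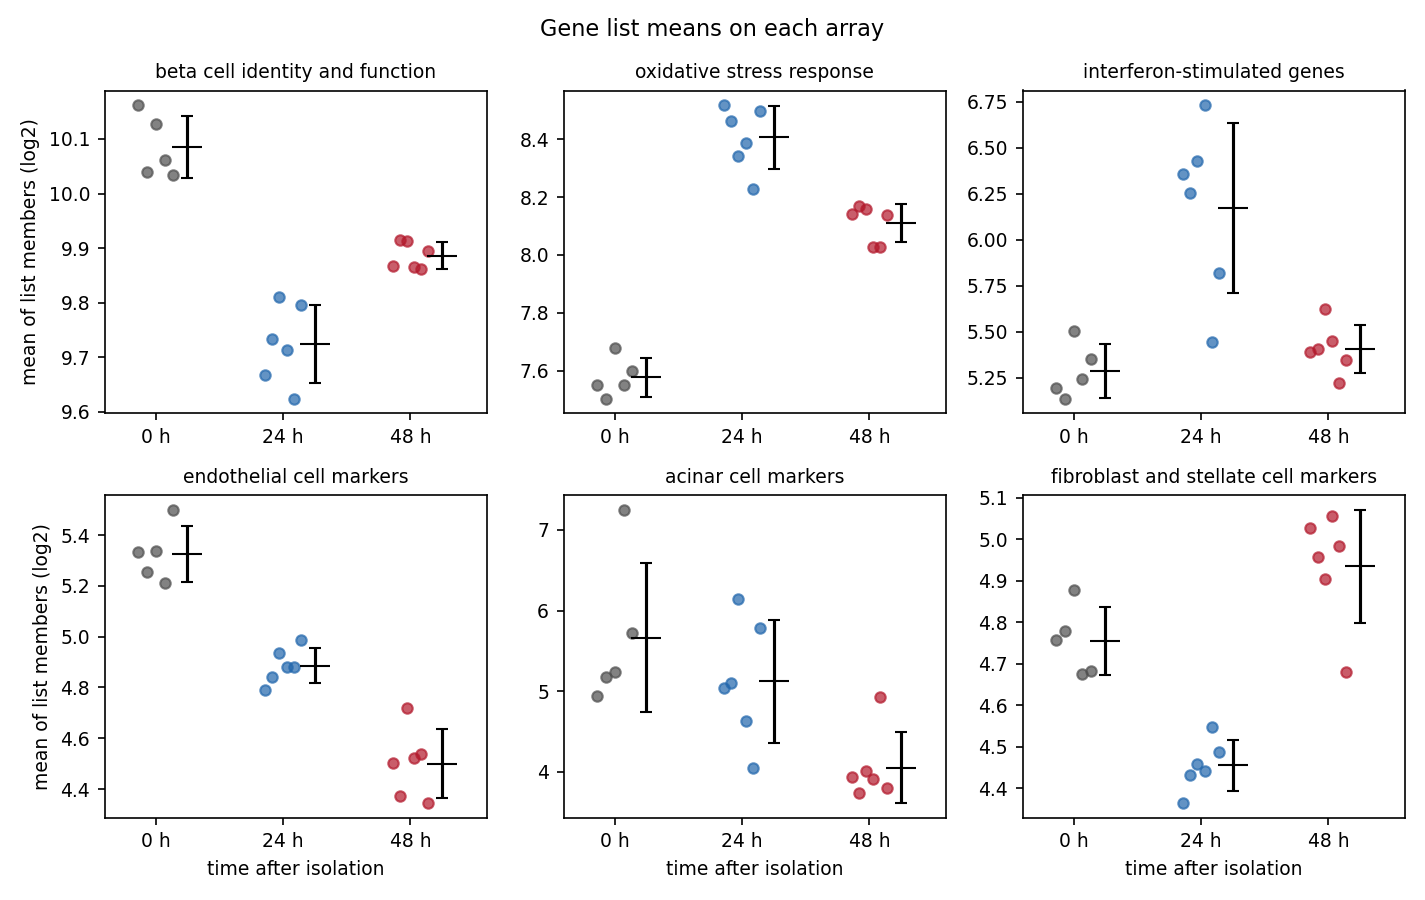
Mean log2 level of the measured members of 6 gene lists on each array (points) by time after isolation, with the mean and SD of each time. The interferon list mean is 5.29 at 0 h, 6.17 at 24 h and 5.41 at 48 h; the endothelial list mean falls from 5.33 to 4.89 and 4.50, and that of the fibroblast list goes from 4.75 to 4.45 and 4.94.

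Macrophage and dendritic cell markers went both ways, with 2 of 22 higher and 2 lower at 48 h than at 24 h (8 and 4 adjusted over the list alone, median 0.29, camera adjusted p = 0.00227, adjusted p = 0.300 with an estimated correlation). Lyz2 and Laptm5 (0.65 ± 0.11) rose, and H2-Aa (-0.88 ± 0.18) and H2-Eb1 (-0.81 ± 0.13) fell. Probe sets of Laptm5 ranged from -0.29 to 0.65. The call of H2-Aa was lost in 8 of the 17 fits that left out 1 array (highest adjusted p = 0.0743, without 24 h replicate 3). Acinar markers had 0 members past the test in either direction (1 up and 8 down adjusted over the list alone), with a median of -0.89 (camera adjusted p = 3.38e-08, adjusted p = 0.245 with an estimated correlation).

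The interferon-stimulated and oxidative stress lists, which had risen at 24 h, were lower at 48 h than at 24 h. Of 18 interferon-stimulated genes, 5 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.75, camera adjusted p = 1.34e-16, adjusted p = 0.0596 with an estimated correlation), among them Bst2 (-0.84 ± 0.14) and Psmb9 (-0.51 ± 0.08). The list mean was lower in 6 of 6 batches. Of 19 oxidative stress genes, 3 fell and 0 rose (8 and 0 adjusted over the list alone, median -0.30, camera adjusted p = 9.31e-08, adjusted p = 0.00935 with an estimated correlation). Besides Hmox1 these were Srxn1 (-0.56 ± 0.10, adjusted p = 0.0178, lost without 48 h replicate 2 at 0.0549) and Gstm1 (-0.40 ± 0.09, adjusted p = 0.0494, or 0.0570 with the batch as a block and 0.111 without 24 h replicate 2). The p53 target genes had 0 members past the test (0 up and 2 down adjusted over the list alone, median -0.14, camera adjusted p = 0.0314, adjusted p = 0.245 with an estimated correlation), a call lost in 5 of the 17 fits that left out 1 array (highest adjusted p = 0.0917, without 24 h replicate 1).

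Of 29 chemokines and cytokines, 1 fell and 0 rose between 24 and 48 h (4 and 0 adjusted over the list alone, median -0.04, camera adjusted p = 0.0493, adjusted p = 0.110 with an estimated correlation), namely Ccl5 (-0.97 ± 0.16). The chemokine call was lost in 10 of the 17 fits that left out 1 array (highest adjusted p = 0.0949, without 24 h replicate 4), and the median was -0.05 without 48 h replicate 6. The 21 NF-kappaB target genes had 0 members past the test (0 up and 4 down adjusted over the list alone, median -0.10, camera adjusted p = 0.0152, adjusted p = 0.254 with an estimated correlation). That call was lost without 24 h replicate 4, where the adjusted p was 0.0672 and the median -0.05. Of 16 pro-apoptotic genes 1 fell, Pmaip1, whose level was not separated from background at either time, and the list did not pass (2 down and 0 up adjusted over the list alone, median 0.00 and mean -0.06, of opposite sign, camera adjusted p = 0.189).

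Beta cell genes were higher at 48 h than at 24 h as a list, although 0 of 21 passed singly (6 up and 0 down adjusted over the list alone, median 0.12, camera adjusted p = 0.000290, adjusted p = 0.106 with an estimated correlation). The list mean was 10.08 ± 0.06 (SD, n = 5) at 0 h, 9.72 ± 0.07 (SD, n = 6) at 24 h and 9.89 ± 0.02 (SD, n = 6) at 48 h, and it was higher at 48 h than at 24 h in 6 of 6 batches. Slc2a2 stood at 0.30 ± 0.07 (adjusted p = 0.0808). Pdx1 (0.24), Ins2 (-0.04), Iapp (-0.10), Gcg (-0.12), Sst (-0.03), Ppy (0.34) and Actb (0.11) did not pass. The other endocrine genes (0 of 9, 0 up and 1 down adjusted over the list alone, median 0.09, camera adjusted p = 0.794), glycolytic genes (0 of 14, 0 adjusted over the list alone, 0.03, 0.985), unfolded protein response genes (0 of 20, 1 up adjusted over the list alone, 0.00, 0.253) and cell cycle genes (0 of 23, 0 adjusted over the list alone, median 0.04, mean of the opposite sign, 0.985) did not pass.

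Between 24 and 48 h, 200 probe sets passed, of which 120 rose and 80 fell, and 27 changed at least 2-fold (15 up, 12 down). By the probe set that represents them, 138 genes passed. No overlap was seen for 254 of 11931 genes above the median level (0.216% by chance), and 113 of these passed. The count of 200 was 102 without 48 h replicate 2 and 263 without 24 h replicate 5, and the 2-fold count of 27 was 16 and 54 without these arrays in turn. Camera called 14 lists, of which the endothelial, fibroblast and oxidative stress lists held with an estimated correlation. By fry 10 passed. The acinar (adjusted p = 0.0635), macrophage (0.0534), NF-kappaB and immediate early (0.197) lists did not.

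Of the probe sets that passed against 0 h, 1218 were higher and 1118 lower at both 24 and 48 h, 4 went in opposite directions, 1522 passed at 24 h only and 1475 at 48 h only. Independent lists of these sizes would share 81.1 higher and 80.8 lower. With the 0 h arrays split between the comparisons, in 20 ways, 456 to 602 were shared higher and 412 to 506 lower. The log2 differences of both comparisons correlated across probe sets at 0.82 against a mean of 0.545 in 50 simulations of unchanged groups with the same 0 h arrays, and their covariance was 0.0631 against 0.00912, a difference of 0.0539; with split 0 h arrays the median covariance was 0.0534.

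The study's design text selects genes whose mean signal at 24 or 48 h differed more than 4-fold from that at 0 h. On the linear scale 153 probe sets met this rule at either time, 53 above and 100 below, and 117 of them passed an adjusted p of 0.05 at 24 or 48 h. At 24 h 43 were above 4-fold and 59 under 0.25-fold; at 48 h the counts were 34 and 93. Both times were above for 24 probe sets and below for 52. The count of 153 was 133 without 0 h replicate 3 and 113 with means of log2 values. Probe sets under 0.25-fold that passed at neither time included those of Fabp1 (0.0319-fold at 24 h, adjusted p = 0.475), Fabp2 (0.0245-fold, 0.498) and Cyp3a11 (0.0294-fold, 0.363). For these the large fold had no support from the test.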

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

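The rule for single arrays was set before the data were examined, and the tests of whether the members of a list moved alike, of dilution by other cells, of more leukocytes and of other splits of the arrays were chosen only after the result was seen. An array was set apart when its gap to the nearest other array of its time, as a share of the range of that time, passed the critical value of Dixon's ratio at 0.05. This happened in 49 of 570 groups of arrays, against 28.5 by chance (1 in 20), for 37 levels of named genes, 9 list means and 3 measures of array quality. The arrays set apart most often were 24 h replicate 5 (9 times) and 0 h replicate 3 (8 times).

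At 24 h, replicate 5 was low for Lcn2 (3.66), 2210010C04Rik (2.10), Krt18 (9.89), Cldn7 (9.32) and Tek (3.95), and for the means of the anti-apoptotic list (6.60) and the tight junction list (6.93). Its array median of 3.57 was the highest of its time and its median correlation with the other 24 h arrays, 0.988, the lowest. Epithelial genes (Krt18, Cldn7), an acute phase gene (Lcn2) and an acinar enzyme gene (2210010C04Rik) were thus low on the same array, but the shift was not limited to them. The upper quartile of this array was 5.76, against 5.93 to 5.98 on the other 24 h arrays. Some lists of high level, such as the beta cell (9.62) and mitochondrial (9.74) lists, had their lowest 24 h mean on it. The dim lymphocyte (3.47) and Schwann cell (3.86) lists had their highest 24 h mean there. At 0 h, replicate 3 was low for Slc2a2 (12.12) and in its correlation with its own time (0.987), and high for Ins2 (13.81), the duct gene Krt7 (9.55), the laminin gene Lama5 (8.04), Cryab (4.74) and the means of the Schwann cell list (3.97) and the acute phase list (3.74).

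At 48 h, replicate 5 was high for the acinar genes Cpb1 (5.45), Cela2a (5.44) and 2210010C04Rik (5.14), for the acinar list mean (4.93) and for Clec7a (7.71). Replicate 3 at 48 h was high for Cfb (8.78), Irf7 (4.97), Iapp (13.10) and the means of the acute phase list (4.74) and the pro-apoptotic list (5.31). Replicate 6 at 48 h was low for Vim (6.61), Nid1 (4.93), Sod2 (10.13) and Cyc1 (9.63) and high for Cdkn1a (8.87). Replicate 1 at 48 h was low for Clps (2.60) and high for Cryab (3.71), replicate 2 was low for Ttr (12.38) and replicate 4 was low for Cyb5r1 (6.31).

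At 24 h, replicate 1 was high for the glycolytic genes Aldoa (12.43), Pgk1 (11.88) and Pfkp (9.52), and replicate 6 was low for Cxcl16 (5.98) and Hspa4 (8.93) and high for Srxn1 (8.57). At 0 h, replicate 4 was high for Clps (6.39) and Ttr (13.05), replicate 2 was low for Gjd2 (11.21), and replicate 6 was high for Serpina3n (3.51) and the means of the NF-kappaB list (5.62) and the cholesterol list (7.82) and low for Pmaip1 (2.32).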

How the results depend on the processing

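Leaving out the 2 arrays that stand apart and the acinar covariate were chosen only after the result was seen, and the other alternatives before the data were examined. With the batch as a block, 3640 probe sets passed at 24 h against 0 h, 3572 at 48 h against 0 h and 224 at 48 h against 24 h, and the block changed no call of a gene or list named in the text other than those printed beside their results. The comparison of 48 h with 24 h moved most: its count of 200 was 112 with the replicate block without batch 5, 321 with array weights (48 of them 2-fold, against 27), and 324 without the 2 arrays that stand apart (56 of them 2-fold). Leaving out single arrays gave 102 without 48 h replicate 2 (16 of them 2-fold) and 263 without 24 h replicate 5 (54 of them 2-fold), while the counts against 0 h stayed within 3041 to 3869 at 24 h and 2862 to 4221 at 48 h. With the acinar marker mean as a covariate, 1100 probe sets passed at 48 h against 0 h, 25 at 48 h against 24 h (7 of them 2-fold) and 966 were shared by both comparisons with 0 h. As that mean did not overlap between 0 and 48 h, the count of 1100 cannot tell acinar content from time. The covariate also left Cela3b at 0.23 at 48 h against 0 h and the acinar list medians at 0.0183 (24 h against 0 h), -0.0424 (48 h against 0 h) and -0.000545 (48 h against 24 h), as it is that list's own mean. Laptm5 at 48 h against 24 h was -0.29 without _x_at and _s_at probe sets, where another of its probe sets stands for the gene. With an estimated inter-gene correlation 3 lists passed at 24 h and 2 at 48 h against 0 h, and 3 at 48 h against 24 h. The floor before log2 was not run, and the cause of the other moves was not tested. Over all settings and results, genes and lists were compared with the main fit by call and sign. For genes, these stayed the same in 7019 cases. The call was lost in 465 and gained in 14, the value moved in 16 and the sign reversed in 2. For lists the cases numbered 2512, 99, 76, 91 and 3 in the same order. A case counted as the same could still differ in size.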

Other observations

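The explanations by a single array or batch were set out before the data were examined; the tests of more leukocytes, of members falling alike, of dilution and of other splits were chosen only after the result was seen. Genes of the acute phase and complement held some of the largest rises, with 3 of 14 higher and 0 lower at both 24 and 48 h against 0 h (3 and 0 adjusted over the list alone at both). Cfb rose by 2.26 ± 0.43 and 2.95 ± 0.43 and Serpina3n, a secreted protease inhibitor under the table's median at 0 h, by at least 2.24 ± 0.41 and 1.49 ± 0.41, besides Lcn2, and at 48 h Serpina3n lost its call in 6 of the 17 fits that left out 1 array (highest adjusted p = 0.0641, without 0 h replicate 4). The list did not pass (camera adjusted p = 0.0714, 0.125 and 0.826 in the 3 comparisons), and Pigr stood at 1.35 ± 0.53 and 1.43 ± 0.53 without passing. The list's median at 48 h against 0 h was -0.02 and its mean 0.77, and at 48 h against 24 h they were -0.02 and 0.07, of opposite sign. Matrix remodelling genes rose as a list at 48 h against 0 h, with 7 of 27 higher and 1 lower (9 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 0.00227, adjusted p = 0.122 with an estimated correlation). Plat, which encodes tissue plasminogen activator, rose by 1.26 ± 0.15, Adamts1 by 0.83 ± 0.14 and Mmp14 by 0.77 ± 0.17, and Timp3 fell. At 24 h 4 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.02, camera adjusted p = 0.0968), and between 24 and 48 h 1 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.07, camera adjusted p = 0.125).

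Genes of tight junctions and the basement membrane were lower at 48 h than at 0 h, with 5 of 15 lower and 0 higher (6 and 1 adjusted over the list alone, median -0.14, camera adjusted p = 0.0144, adjusted p = 0.203 with an estimated correlation), among them Col4a2 (-0.90 ± 0.17), Lama5 (-0.73 ± 0.16) and Nid1 (-0.60 ± 0.10). Between 24 and 48 h 1 fell, Lamb1 (-0.62 ± 0.09), and 0 rose (4 and 0 adjusted over the list alone, median -0.18, camera adjusted p = 0.00347, adjusted p = 0.122 with an estimated correlation). At 24 h 2 rose and 2 fell (2 and 2 adjusted over the list alone, median -0.14, camera adjusted p = 0.603). Cholesterol genes fell as a list between 24 and 48 h (1 of 16 lower, 4 adjusted over the list alone, 0 higher, median -0.17, camera adjusted p = 1.78e-05, adjusted p = 0.0552 with an estimated correlation), after medians of 0.12 at 24 h (2 rose and 1 fell, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0968) and -0.13 at 48 h against 0 h (1 rose and 3 fell, 2 and 4 adjusted over the list alone, camera adjusted p = 0.373). Immediate early genes were lower at 48 h than at 24 h (1 of 24 fell and 0 rose, 2 and 1 adjusted over the list alone, median -0.16, camera adjusted p = 0.0153, adjusted p = 0.375 with an estimated correlation). That call was lost in 2 of the 17 fits that left out 1 array (highest adjusted p = 0.0690, without 48 h replicate 1), and the median was -0.25 without 24 h replicate 5. Against 0 h 6 rose and 2 fell at 24 h (6 and 4 adjusted over the list alone, median 0.10, camera adjusted p = 0.125) and 6 rose and 3 fell at 48 h (6 and 6 adjusted over the list alone, median -0.04 with a test pointing up, camera adjusted p = 0.968). Ier3 rose by 2.37 ± 0.20 and 1.90 ± 0.20 at these times, whereas Gadd45b fell by 1.69 and 1.99 on the log2 scale.

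Of 10 duct markers 3 rose at 24 h (3 adjusted over the list alone, median 0.06, camera adjusted p = 0.109) and 2 at 48 h against 0 h (3 up and 1 down adjusted over the list alone, median -0.08 with a test pointing up, camera adjusted p = 0.509), with Krt7 at 1.19 ± 0.10 and 0.87 ± 0.10. The duct list mean on 0 h replicate 3 was 7.42, the highest of all arrays, and without that array the medians were 0.11 (camera adjusted p = 0.0202) and -0.02 (0.198). Between 24 and 48 h 0 passed (1 down adjusted over the list alone, median -0.10, camera adjusted p = 0.0641, or 0.0439 with the batch as a block and 0.0311 without 0 h replicate 3). Of 5 blood cell and adipocyte markers, the fatty acid binding protein gene Fabp4 rose by 1.27 ± 0.13 at 24 h (1 up and 1 down adjusted over the list alone, list median 0.04, camera adjusted p = 0.185) and fell by 0.85 between 24 and 48 h (1 down adjusted over the list alone, median -0.07, camera adjusted p = 0.0493, adjusted p = 0.237 with an estimated correlation). That call was lost in 9 of the 17 fits that left out 1 array (highest adjusted p = 0.102, without 24 h replicate 5), where the median was -0.04. At 48 h against 0 h 0 passed (1 up and 1 down adjusted over the list alone, median 0.03, camera adjusted p = 0.794). Of 17 hypoxia-induced genes 2 rose and 1 fell at 24 h (3 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0622, or 0.0210 with the batch as a block), with Ddit4 at 1.45 ± 0.33. At 48 h against 0 h 1 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.0808, or 0.0268 with the batch as a block), and 0 passed between 24 and 48 h (0 adjusted over the list alone, median -0.01, camera adjusted p = 0.603).

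The remaining lists did not pass in any comparison. Of 19 secretory granule genes 3 fell at 24 h, Rab3a by 0.55 (SE 0.09), Ptprn2 by 0.46 and Rims2 by 0.46 (1 up and 6 down adjusted over the list alone, median -0.04, camera adjusted p = 0.189), and at 48 h 2 rose and 2 fell (3 and 4 adjusted over the list alone, median -0.09, camera adjusted p = 0.385), with Chgb at 0.33 ± 0.06. For 14 heat shock genes 2 rose and 1 fell against 0 h at each time (4 and 1, then 4 and 2 adjusted over the list alone), with medians of 0.06 and 0.13 and means of -0.02 and -0.05, of opposite sign (camera adjusted p = 0.241 and 0.253), and Hspa4 rose by 0.56 ± 0.11 and 0.75 ± 0.11. The mitochondrial respiratory chain (20 genes, 1 and 2 higher, the same adjusted over the list alone, medians 0.06 and 0.05, camera adjusted p = 0.201 and 0.125) and the anti-apoptotic genes (9 genes, 1 higher at each time, 1 up and 2 down then 1 up adjusted over the list alone, medians -0.05 and 0.02, camera adjusted p = 0.764 and 0.532) also stayed near 0, and the latter's riser was Bag3 (0.65 ± 0.13 and 0.55 ± 0.13). Of 11 lymphocyte markers 0 and 1 passed (0 and 1 adjusted over the list alone, medians -0.02 at both times, with a test pointing up at 24 h, camera adjusted p = 0.985 and 0.385), and of 8 Schwann cell markers 1 and 0 (1 and 0 adjusted over the list alone, medians -0.03 and -0.01, camera adjusted p = 0.794 and 0.727). Between 24 and 48 h these 6 lists had 0 members past the test, also adjusted over the list alone, and camera adjusted p = 0.360, 0.968, 0.764, 0.142, 0.175 and 0.941 in the order named, with medians of 0.05, 0.00, -0.01, 0.13, -0.05 and -0.03; for the heat shock and mitochondrial lists mean and median had opposite signs.

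The rise of interferon-stimulated genes at 24 h could come from a single array or batch, from more leukocytes at 24 h, or from a response of the cultured cells. For a single array or batch, the leave-one-out median nearest to 0 was 0.81, without 24 h replicate 4, and 5 of 5 batches were higher, which excluded that explanation. More leukocytes would raise their markers if expression within these cells stayed the same. The median of the macrophage list was -0.54 and that of the lymphocyte list -0.02, so the markers gave no sign of more leukocytes. Only 4 of 11 lymphocyte markers were above the median level, and expression within leukocytes may have changed. More leukocytes were therefore not excluded. The inducing signal was not tested, and 16 of 18 members were above the median level. No gene of this list is held by another list.

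The lower endothelial markers at 48 h may reflect fewer endothelial cells, dilution by other cell types, or changed expression in the cells that remained. If fewer cells were the whole of it, well-expressed markers should fall alike, but 8 members ranged from -2.82 (Ptprb) to -0.24 (Egfl7), with an adjusted one-sided heterogeneity p of 0.00433 over 462 exact permutations; the limit of 2 log2 units of room was set after a first run, which gave 0.00433 over the 12 of 17 members above the median level. Dilution should lower fibroblast markers as much, but the fibroblast minus endothelial difference of each array's median member level, every member centred on its own mean, was 0.59 higher at 48 h (SE 0.0752, exact permutation two-sided p = 0.00216). Egfl7, Eng and Esam may also be expressed by other islet cells; the 5 members left without them ranged from -2.82 to -1.25 (unadjusted one-sided exact permutation heterogeneity p = 0.00216). The fibroblast list is no fixed reference, as it fell at 24 h (median -0.16) and rose between 24 and 48 h (median 0.18). Its difference from the endothelial list therefore cannot exclude dilution. The measured falls were not alike, but probe background compresses large falls. Loss of endothelial cells, alone or with changed expression, remains possible. No gene of this list is held by another list.

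For the acinar markers at 48 h, a single array or batch, fewer acinar cells with all markers falling alike, and a fall of transcripts within acinar cells were weighed. The leave-one-out median nearest to 0 was -0.96, without 0 h replicate 4, so a single array or batch was excluded although that array carried much of the size. The fall of 10 members ranged from -4.16 (Cpb1) to -0.42 (Bhlha15), with an adjusted one-sided heterogeneity p of 0.00433 over exact permutations, and 0.00866 over the 17 of 22 members above the median level in the first run. Bhlha15 is also expressed outside acinar cells and probe background compresses large falls, so loss of acinar cells remains possible. No gene of this list is held by another list.

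Other splits of the arrays into groups of the same sizes were tried, 100 of the 462 possible per comparison, the real one counted. At 24 h against 0 h, 1 split (the real one) gave as many as 3862 probe sets or 497 at 2-fold, with 2258 and 320 as the highest of the others. At least 14 lists were given by 6 splits, the real one counted (highest 17). The others among these 6 kept 5, 2 or 1 of the 6 arrays of 24 h in their group. They were thus partly copies or mirror images of the real split, and cannot tell whether chance gives as many lists. Splits that kept 3 or 4 of these arrays gave at most 13 lists. The counts of 2258 and 320 came from splits whose 24 h group held 1 array of 24 h and all 5 of 0 h, near mirror images of the real one. Without such splits the highest counts were 125 and 62. At 48 h against 0 h, 1 split gave as many as 3815 or 419, with 0 as the highest of the others for both, and 4 gave at least 12 lists (highest 13). At 48 h against 24 h, 1 split gave as many as 200 or 27, with 167 and 12 as the highest of the others, and 2 gave at least 14 lists (highest 15). Among the 5, 7 and 8 other splits that part as many pairs of arrays of the same batch, the highest counts of probe sets were 0, 0 and 2. Their highest counts of lists were 12, 8 and 10, against 14, 12 and 14 in the real splits. At 48 h against 24 h, a split that kept 3 of the 6 arrays of 48 h in their group called 11 lists with 0 probe sets. A camera call at the preset correlation is thus weak evidence by itself.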
